A study of Homo sapiens with 8 samples.

How the data were processed

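Gene expression was measured in 8 libraries of JHH-6 hepatocellular carcinoma cells, 4 with scramble control siRNA and 4 labelled siAPE1, at 100 pmol of siRNA and collected on day 2. Per the labels' protocols, RNA was isolated with a miRNeasy kit, libraries were made with a SMARTer small-RNA kit altered to also catch primary miRNA transcripts, and sequencing was single-end at 100 bp. The authors deposited 1 table of whole-number counts per gene with Ensembl identifiers, gene symbols and transcript biotypes. Per the submitters' processing notes, CASAVA, STAR 2.5.3a, DESeq2 and the GRCh38 build were used, with no role or order given. The counting tool, the annotation release, trimming, the strand setting, and the handling of reads that map to several places or overlap several genes are not given in the sources used here. Reads of near-identical copies and of overlapping genes can therefore be split, shared or left out, which matters most for short RNAs, histones and miRNA genes within other genes. Groups and replicate numbers came from sample titles. The series' design text speaks of 3 replicates where there were 4 libraries per group, and the description of 1 library repeats a replicate number that its title does not bear, so titles were used.

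The table had 58302 rows, of which 37453 carried a symbol, 4551 were named from a reference table of gene names, 16298 had no name and 36281 had no count in any library. No column lacked a sample. Library totals were the column sums, 2141220, 2272150, 2257520 and 1911397 for scramble replicates 1 to 4 and 1641914, 1637782, 1631206 and 1648413 for siAPE1 replicates 1 to 4. A count of 0 allows up to 3 counts, or 1.32 to 1.84 CPM by library. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries of a group were compared pairwise over genes with at least 20 counts in the pair: chi-square per degree of freedom was 1.81 to 5.30, so none was a repeat deposit.

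The comparison was libraries labelled siAPE1 over scramble, with no covariate. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 6808 genes, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 folds were the absolute log2 fold divided by the square root of F. CPM values are TMM-scaled and, with SD, over 4 libraries. The common biological coefficient of variation was 8.47%. Gene lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2, correlation preset at 0.01), for the 26 of 33 lists with at least 5 tested members. Camera with an estimated correlation and fry were alternatives. Shares of counts per RNA class were compared by a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

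Genes were named by rule. It took APEX1, then the 10 largest rises and 10 largest falls among symbols with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups. It also took the 10 miRNA genes with the smallest p, 9 miRNA genes chosen in advance where tested, and the 3 members of each list with the smallest p. Members left unnamed are given as counts, and 2 genes are not reported here by name. Locations came from RefSeq on GRCh38.p14, matched by symbol for 98.2% of tested genes.

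The fit was checked on simulated counts for the same 6808 genes with 200 of them changed. It recovered 14% of genes changed 1.3-fold, 44% at 1.5-fold, 84% at 2-fold and 96% at 3-fold, with 7 false calls among 126 and no wrong sign. In this simulation most genes changed 1.5-fold or less were thus missed. The data gave 756 calls, not 126, so the cutoff on unadjusted p was looser there and more such changes could be called. In the list test, a simulated list of 25 genes shifted 1.3-fold was called and 0 unshifted lists were. The simulated genes varied independently, so this did not check the list test where members vary together, as they may in the data. Alternatives were RLE, upper-quartile and total-count scaling, no filter, a stricter filter (at least 10 counts in every library of a group and a mean of 50), DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, leaving out mitochondrial, rRNA and short non-coding classes, a test against 1.2-fold (glmTreat), a fit to miRNA genes alone, and another denominator for shares. Thinning all libraries to equal totals and leaving APEX1 out were added after seeing the data. Tables and plots used Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Read positions were not analysed here.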

Results

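The data were gene-level read counts from 8 libraries of JHH-6, a hepatocellular carcinoma cell line. In 4 libraries the cells had received a scramble (non-targeting) control siRNA, and 4 libraries were labelled as siRNA against APE1, each at 100 pmol with collection on day 2 after transfection. APE1, encoded by APEX1, is the apurinic/apyrimidinic endonuclease of base excision repair. The libraries were made from total RNA with a small-RNA kit modified to keep longer miRNA precursors, and the stated aim was to find miRNAs that change on APE1 silencing. Total counts were 1911397 to 2272150 in the scramble libraries and 1631206 to 1648413 in those labelled siAPE1, so the groups did not overlap in depth. On average 15401 ± 117 genes had a count in the scramble libraries and 14742 ± 54.3 in those labelled siAPE1 (SD, n = 4 each). The labels do not say that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

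APEX1 counts were higher, not lower, in the libraries labelled siAPE1. APEX1 (ENSG00000100823; GRCh38 chromosome 14, 20455226 to 20457767) had 177, 187, 203 and 160 counts in scramble replicates 1 to 4. It had 9358, 12811, 11223 and 9161 counts in replicates 1 to 4 labelled siAPE1. Its level was 84.3 ± 4.92 CPM with scramble siRNA and 6768 ± 1282 CPM in the libraries labelled siAPE1 (SD, n = 4 each), 80.1-fold higher (log2 fold 6.32 ± 0.14 SE, adjusted p = 1.38e-29, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). All 4 libraries of each label lay on the same side. Because counts of the targeted gene rose where the label calls for a fall, samples are named by label throughout, and every direction given here is that of the labels. The counts do not show whether APEX1 mRNA was lower in these cells.

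**Figure D1:**
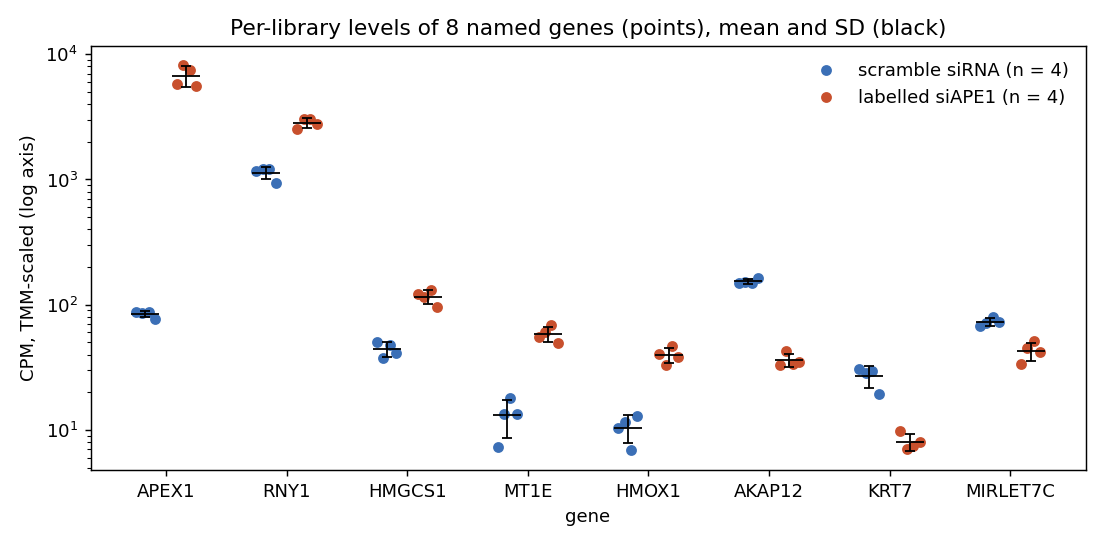
TMM-scaled CPM (log axis) of 8 named genes in each library, with scramble siRNA in blue and libraries labelled siAPE1 in orange; black bars are the mean and SD of 4 libraries. APEX1 lay at 84.3 CPM on average with scramble siRNA and at 6768 CPM in the libraries labelled siAPE1. The groups did not overlap for any of the 8 genes, as the naming rule required of the largest rises and falls.

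Beyond APEX1, genes rose and fell in near equal number in the libraries labelled siAPE1. MT1E, a metal-binding metallothionein, rose from 13.1 ± 4.38 to 58.5 ± 8.01 CPM, and HMOX1, which degrades haem, rose from 10.4 ± 2.62 to 39.7 ± 5.67 CPM (SD, n = 4 each). AKAP12, a scaffold for protein kinase A, fell from 154 ± 6.59 to 36.1 ± 4.50 CPM, and the epithelial keratins KRT7 and KRT80 fell from 27.1 ± 5.32 to 8.05 ± 1.26 CPM and from 20.5 ± 3.66 to 6.55 ± 2.00 CPM. In all, 756 of 6808 genes tested passed an adjusted p of 0.05, 379 higher and 377 lower by label, of which 45 and 71 changed at least 2-fold. Among protein-coding genes, 295 were higher and 363 lower of 6258 tested.

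After APEX1, the largest rises were those of MT1E (log2 fold 2.13 ± 0.16 SE), HMOX1 (1.93 ± 0.17), a Y RNA copy known only by its identifier (ENSG00000201820, 1.66 ± 0.27), NKX2-3 (1.51 ± 0.23), DYRK2 (1.51 ± 0.26), HMGCS1 (1.39 ± 0.11), SLC25A18 (1.35 ± 0.31), RNY1 (1.33 ± 0.10) and E2F7 (1.29 ± 0.28). NKX2-3 is a homeobox transcription factor, DYRK2 a protein kinase and E2F7 a repressor of cell cycle genes. The largest falls were those of AKAP12 (-2.09 ± 0.11), MRPS16 (-1.97 ± 0.16), GBP1 (-1.91 ± 0.32), CREBL2 (-1.90 ± 0.34), ATP6V1B2 (-1.79 ± 0.31), TMEM173 (-1.77 ± 0.32), KRT7 (-1.74 ± 0.21), KRT80 (-1.65 ± 0.23), S100A16 (-1.62 ± 0.25) and GPX1 (-1.61 ± 0.33). MRPS16 is a mitochondrial ribosomal protein, GBP1 an interferon-inducible GTPase, TMEM173 the cytosolic DNA sensor adaptor STING and GPX1 a glutathione peroxidase. Adjusted p-values of these genes lay between 3.39e-17 for AKAP12 and 0.00285 for SLC25A18 (edgeR, Benjamini-Hochberg). As the naming rule required, the 4 values of one label did not overlap the 4 of the other. Such separation held for 1024 of all genes tested (15.0%), where chance gives 2.86%. Several named folds rest on few reads in the lower group. In the libraries labelled siAPE1, GBP1 had 5, 2, 3 and 9 counts and CREBL2 2, 6, 5 and 5. ATP6V1B2 had 4, 5, 4 and 6 there, TMEM173 6, 5, 5 and 3, and GPX1 4, 7, 6 and 8. In the scramble libraries SLC25A18 had 10, 7, 6 and 6. Some of these values lie at or under the limit of 3 counts, so the sizes of such folds are uncertain. DESeq2 called 260 genes, 134 higher and 126 lower, and scaling on total counts alone called 702, 260 higher (37.0%, against 50.1% with TMM).

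Among miRNA genes, the aim of the study, changes were few and small. Most called miRNA genes were lower in the libraries labelled siAPE1, where APEX1 counts were higher rather than lower. MIRLET7C, of the let-7 family, fell from 72.9 ± 4.74 to 42.8 ± 7.10 CPM (log2 fold -0.77 ± 0.11 SE, adjusted p = 6.40e-06), and MIR877 fell from 49.1 ± 7.46 to 29.7 ± 3.25 CPM (-0.73 ± 0.13, adjusted p = 0.000172; SD, n = 4 each, edgeR with Benjamini-Hochberg adjustment). MIR3609 rose from 17.8 ± 5.30 to 30.0 ± 3.03 CPM (0.74 ± 0.17). MIR769 fell with a log2 fold of -1.07 ± 0.32, MIR331 with -0.55 ± 0.15, MIR186 with -0.51 ± 0.14, MIR210 with -0.50 ± 0.15 and MIR744 with -0.36 ± 0.11, while MIRLET7A1 rose with 0.35 ± 0.12. MIR769 rests on few reads, 19, 20, 22 and 11 counts with scramble siRNA and 4, 4, 7 and 10 in the libraries labelled siAPE1. CPM values of the groups overlapped for MIR769 and MIR744. MIR210 is known as a hypoxia-induced miRNA.

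Of 1879 miRNA genes in the table, 468 had a count, 94 were tested and 9 were called, 2 higher and 7 lower. Adjusted over the list alone, 9 were called as well, and 22 had an unadjusted p under 0.05. A fit to miRNA genes alone tested 97 and called 6, of which 4 were higher (MIR25, MIR3609, MIRLET7F1 and MIR29A, of which MIRLET7F1 and MIR29A were named after their values were seen) and 2 lower (MIRLET7C and MIR877). That fit differed in gene set, scaling, estimated variance and adjustment together. Adjustment over the list alone left the main fit at 2 higher and 7 lower, so by itself it did not move the balance. The SE of MIR25 was 0.095 in the main fit and 0.065 in the fit to miRNA genes alone. The parts of scaling and variance were not separated. RLE and upper-quartile scaling of all genes called the same 9 miRNA genes, total-count scaling 8 of them without MIRLET7A1 (adjusted p = 0.181), and thinned libraries, an alternative added after seeing the data, 6 of them without MIR769 (0.0656), MIR744 (0.0977) and MIRLET7A1 (0.126). MIR25 had a log2 fold of 0.27 ± 0.09 with an adjusted p of 0.0663 over all genes, and 0.0399 with limma-voom. With limma-voom MIR769 lost its call (adjusted p = 0.0515). DESeq2 called MIRLET7C and MIR877 and no other miRNA gene.

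MIRLET7C, MIR877 and MIR3609 stayed called whichever library was left out. MIR331 lost its call without scramble replicate 2 (adjusted p = 0.0931, edgeR). MIR186 lost it without siAPE1 replicate 3 (0.0823) and in 2 of the 8 omissions in all. MIR769, MIR210 and MIR744 lost it in 5, 6 and 5 omissions, each with the highest adjusted p without siAPE1 replicate 2 (0.117, 0.126 and 0.132). MIRLET7A1 lost it in 6, with the highest without siAPE1 replicate 3 (0.133), and also with the replicate block (0.0545) and with no filter (0.213). Gene-level counts do not separate the arms of a hairpin, nor mature from primary miRNA, and copies of a family with like sequences, such as let-7, may share reads.

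Of the miRNA genes named in advance, MIR33A had a log2 fold of 0.29 ± 0.27 (adjusted p = 0.569), MIR221 of -0.09 ± 0.09 (0.631), MIR222 of -0.18 ± 0.09 (0.252) and MIR27A of -0.23 ± 0.13 (0.281, edgeR), and none of these 4 passed, while MIR769, also named in advance, did (-1.07 ± 0.32, 0.0274). MIR222 was abundant, with 846 ± 77.3 and 746 ± 64.4 CPM (SD, n = 4 each). MIR21, MIR34A, MIR92B and MIR122 were listed with 0 counts in all 8 libraries, which allows up to 1.32 to 1.84 CPM per library, counting 3 reads as the upper limit for counting error only. The limit does not bound a gene whose reads went uncounted for overlap with another gene, as may be so for MIR21, which lies in VMP1. Of the 21 tested genes of miRNA biogenesis, TNRC6B (log2 fold 0.67 ± 0.11) and DICER1 (0.69 ± 0.14) rose, 19 did not pass, and the list did not pass (adjusted p = 0.836, limma camera). Of 6 miRNA host transcripts, MIR222HG rose (0.87 ± 0.26) and 5 did not pass (list adjusted p = 0.253). The call of MIR222HG was lost in 5 omissions, with an adjusted p of 0.118 without siAPE1 replicate 2.

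**Figure D2:**
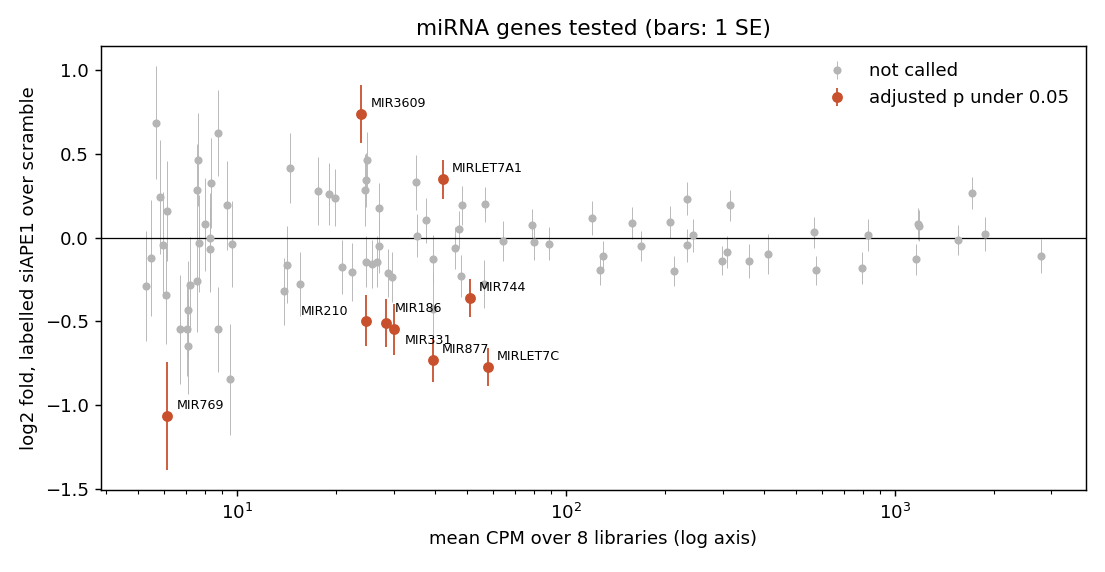
Log2 fold of each of the 94 tested miRNA genes (libraries labelled siAPE1 over scramble, bars 1 SE) against its mean CPM over 8 libraries (log axis); the 9 called genes are in orange. All 9 called genes, 2 higher and 7 lower, had a mean under 100 CPM. MIR25, among the most abundant, had a log2 fold of 0.27 and did not pass with edgeR over all genes, though it did in the fit to miRNA genes alone.

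In cholesterol biosynthesis, 12 of 21 tested genes rose in the libraries labelled siAPE1 and none fell. HMGCS1, HMG-CoA synthase, rose from 44.2 ± 5.83 to 116 ± 14.9 CPM (log2 fold 1.39 ± 0.11 SE), SQLE, squalene epoxidase, from 64.2 ± 5.15 to 101 ± 3.57 CPM (0.66 ± 0.10), and FDPS, farnesyl diphosphate synthase, from 55.4 ± 4.51 to 81.9 ± 2.02 CPM (0.57 ± 0.10; SD, n = 4 each). Adjusted over the list alone, 16 members were called, all higher. The list median was 0.55, with an adjusted p of 1.26e-10 by camera and of 0.00771 with an estimated correlation. It was the 1 list of the 10 called by camera whose call held with an estimated correlation, and all 10 had higher members on balance. The direction is by label, and APEX1 counts rose where that label calls for a fall.

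Chaperones of the unfolded protein response had 4 of 14 members higher and none lower, and 6 when adjusted over the list alone (list median 0.27, adjusted p = 0.00274 by camera, adjusted p = 0.186 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP, rose with a log2 fold of 0.42 ± 0.10, SEL1L with 0.74 ± 0.17 and SDF2L1 with 1.02 ± 0.25, while DESeq2 gave adjusted p-values of 0.102, 0.0692 and 0.0761. Among ATF4 targets, DDIT4 (0.46 ± 0.09) and SLC7A5 (0.49 ± 0.13) rose and the cystine transporter SLC7A11 fell (-0.36 ± 0.10), with 3 of 13 higher and 1 lower, 4 and 1 adjusted over the list alone, and a list adjusted p of 0.0738 (0.0499 without siAPE1 replicate 2). SLC7A5 had an adjusted p of 0.124 with DESeq2, and SLC7A11 one of 0.0521 without siAPE1 replicate 4.

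Genes of the cell cycle were higher in part. Of 20 DNA replication and G1/S genes 4 rose (5 adjusted over the list alone) and none fell, among them RRM2, a ribonucleotide reductase subunit (log2 fold 0.80 ± 0.19 SE), MCM10 (1.02 ± 0.26) and GINS1 (1.00 ± 0.27), with a list median of 0.29, an adjusted p of 0.00160 by camera and an adjusted p of 0.186 with an estimated correlation. DESeq2 gave RRM2, MCM10 and GINS1 adjusted p-values of 0.0603, 0.0948 and 0.126, and GINS1 had 0.0510 without scramble replicate 2. Of 25 G2/M and mitosis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone): NUSAP1 (0.65 ± 0.12) and CENPF (0.40 ± 0.09) rose, and the mitotic kinase AURKA fell (-0.63 ± 0.16), with a list adjusted p of 0.0106 and an adjusted p of 0.361 with an estimated correlation. AURKA had an adjusted p of 0.0723 without siAPE1 replicate 2. Of 31 replication-dependent histone genes, whose mRNAs lack poly(A) tails, 16 rose and none fell, and 23 when adjusted over the list alone (median 0.38, adjusted p = 1.07e-08, adjusted p = 0.210 with an estimated correlation). HIST1H3B (0.53 ± 0.10), HIST4H4 (0.65 ± 0.13) and HIST1H4B (0.50 ± 0.11) were the 3 with the smallest p. Histone copies of like sequence may share reads.

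**Figure D3:**
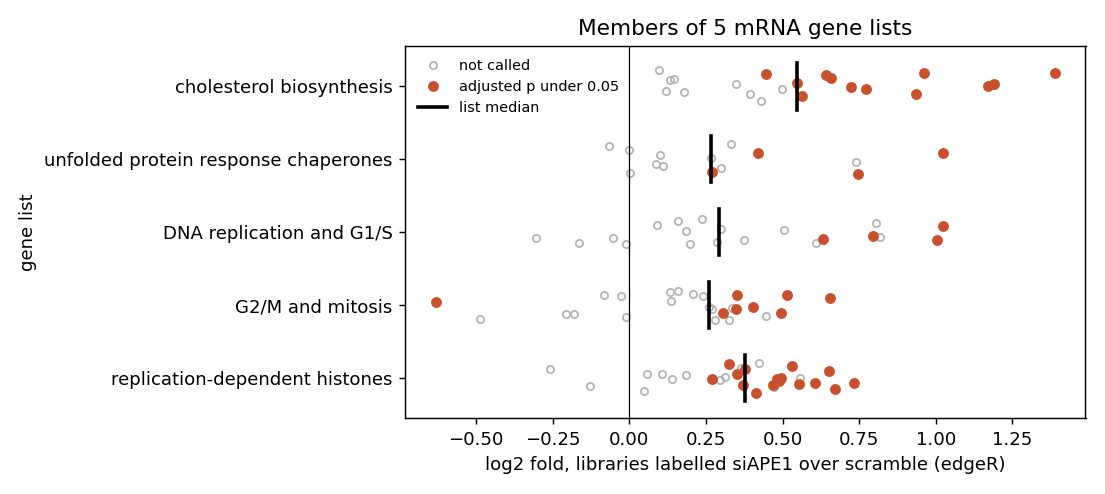
Log2 fold (libraries labelled siAPE1 over scramble, edgeR) of the tested members of 5 gene lists; filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. Vertical scatter within a list is for legibility; the median was 0.55 for cholesterol biosynthesis and 0.26 to 0.38 for the other 4 lists.

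Among short RNAs, Y RNAs, components of Ro ribonucleoproteins, were the most changed. RNY1 rose from 1135 ± 130 to 2846 ± 262 CPM, RNY3 from 2347 ± 250 to 5278 ± 520 CPM and RNY4 from 147 ± 24.5 to 347 ± 60.3 CPM in the libraries labelled siAPE1 (SD, n = 4 each), log2 folds of 1.33 ± 0.10, 1.17 ± 0.10 and 1.23 ± 0.11 SE. Of 48 Y RNA genes 16 rose and none fell, and 22 when adjusted over the list alone (median 0.51, adjusted p = 1.51e-12 by camera, adjusted p = 0.186 with an estimated correlation). Most of the 48 are copies of like sequence that may share reads, so their number is uncertain. The summed Y RNA share of counts was 0.495 ± 0.0373% with scramble siRNA and 0.989 ± 0.0680% in the libraries labelled siAPE1 (SD, n = 4 each), a ratio of 2.00 (p = 0.0286, two-sided exact permutation test, the smallest this design allows; adjusted p = 0.143 over 15 classes).

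Spliceosomal snRNAs had 18 of 64 members higher and none lower, and 24 when adjusted over the list alone (median 0.32, adjusted p = 2.63e-07, adjusted p = 0.524 with an estimated correlation; median 0.21, adjusted p = 0.00243 without scramble replicate 4), with RNU5A-1 (log2 fold 0.84 ± 0.11), RNU5B-1 (0.93 ± 0.13) and RNU4-2 (0.75 ± 0.11) leading. Box C/D snoRNAs had 18 of 74 higher and none lower, and 25 higher and 3 lower when adjusted over the list alone (median 0.20, adjusted p = 8.57e-06, adjusted p = 0.557 with an estimated correlation; median 0.13, adjusted p = 0.0107 without scramble replicate 4), with SNORD8 at 0.68 ± 0.11, SNORD53 at 0.54 ± 0.10 and SNORD63B at 0.54 ± 0.11. Nuclear rRNA genes, mostly 5S copies, had 7 of 22 higher and none lower, and 8 higher and 1 lower when adjusted over the list alone (median 0.27, adjusted p = 0.00118, adjusted p = 0.378 with an estimated correlation), with RNA5SP202 (0.63 ± 0.12), RNA5SP336 (0.63 ± 0.12) and RNA5SP426 (0.59 ± 0.12). Small Cajal body RNAs had 4 of 16 higher (median 0.17, adjusted p = 0.0356, adjusted p = 0.550 with an estimated correlation), led by SCARNA10 (0.82 ± 0.16) and SCARNA5 (0.48 ± 0.10), and this list did not pass with total-count scaling (adjusted p = 0.0602) or without scramble replicate 4 (0.218), siAPE1 replicate 3 (0.0943) or siAPE1 replicate 1 (0.0501). Copies of snRNAs and 5S rRNA may share reads, so these member counts are uncertain too.

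Other short RNA lists did not pass. Box H/ACA snoRNAs had 6 of 62 higher and 1 lower, 7 and 1 when adjusted over the list alone (adjusted p = 0.113), with SNORA2C at 0.55 ± 0.12. This list passed without scramble replicate 1 (adjusted p = 0.00529), scramble replicate 2 (0.0394) or siAPE1 replicate 4 (0.0165). Mitochondrial tRNAs had 4 of 16 higher and 1 lower (adjusted p = 0.113), with MT-TY at 1.05 ± 0.10, MT-TV at 0.61 ± 0.11 and MT-TC at 0.64 ± 0.12, and passed without scramble replicate 1 (adjusted p = 0.00697), scramble replicate 2 (0.0103) or siAPE1 replicate 2 (0.0499). None of 10 tested 7SL and 7SK genes passed (list adjusted p = 0.473). The vault RNA list had 3 tested members and the mitochondrial rRNA list 2, too few for the list test, and none of these passed: VTRNA1-1 had a log2 fold of -0.01 ± 0.16 and MT-RNR2 of -0.03 ± 0.09. Of 13 mitochondrially encoded mRNAs 1 rose, MT-ND6 (0.43 ± 0.11), and 12 did not pass, while adjusted over the list alone 1 was higher and 4 lower (list median -0.15, adjusted p = 0.161). MT-ND6 lost its call in 2 omissions, with an adjusted p of 0.0703 without siAPE1 replicate 2.

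In the makeup of the libraries, mitochondrially encoded mRNAs took 6.36 ± 0.379% of counts with scramble siRNA and 5.33 ± 0.344% in the libraries labelled siAPE1, and 7SL and 7SK RNAs 1.85 ± 0.0809% and 2.09 ± 0.0963% (SD, n = 4 each; p = 0.0286 for both, exact permutation, adjusted p = 0.143). No class passed after adjustment over 15 classes. With 0.0286 as the smallest p, a class could pass only if most of the 15 reached it, so this does not argue against a change in a few classes. miRNA genes took 2.00 ± 0.212% and 1.89 ± 0.0870% (p = 0.429, exact permutation, n = 4 each), box C/D snoRNAs 12.0 ± 0.752% and 12.5 ± 0.341% (p = 0.314, exact permutation), and nuclear protein-coding genes 18.4 ± 1.23% and 18.4 ± 0.639% (p = 0.886, exact permutation). The 5 most abundant features took 42.2 ± 0.455% and 40.3 ± 0.312% of counts. MT-RNR2, a mitochondrial rRNA, and GAS5, a snoRNA host transcript, led them.

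Repair and damage-response lists did not pass by camera in the main fit, and many members had too few counts to be tested. Those tested were 11 of 25 base excision repair genes, 10 of 28 p53 targets and 9 of 22 NF-kappaB targets. Of 11 tested base excision repair genes other than APEX1, PARP2 rose (log2 fold 0.61 ± 0.16 SE) and 10 did not pass (list adjusted p = 0.378, camera). PARP2 lost its call without scramble replicate 2 and without siAPE1 replicate 3 (adjusted p = 0.0552 for the latter). Of 10 p53 targets GADD45A rose (0.62 ± 0.19) and 9 did not pass (list adjusted p = 0.355). GADD45A lost its call in 6 of the 8 omissions, with an adjusted p of 0.155 without siAPE1 replicate 3. Of 9 NF-kappaB targets BIRC3 (0.78 ± 0.21) and SOD2 (0.50 ± 0.16) rose, 3 when adjusted over the list alone, and the list did not pass (adjusted p = 0.0738), though it did without siAPE1 replicate 4 (adjusted p = 0.0416). BIRC3 had an adjusted p of 0.0974 without siAPE1 replicate 1, and SOD2 had one of 0.134 without siAPE1 replicate 3.

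Of 20 NRF2 targets 5 rose and 1 fell (5 and 2 adjusted over the list alone): HMOX1 (1.93 ± 0.17) and AKR1B10 (0.54 ± 0.09) rose, while GCLM, a subunit of the enzyme that makes glutathione's precursor, fell (-0.58 ± 0.09), and the list did not pass (adjusted p = 0.417, camera). Of 17 immediate early and AP-1 genes 2 rose, FOS (0.63 ± 0.11) and DUSP1 (0.47 ± 0.11), and 1 fell, CYR61 (-1.10 ± 0.11), or 5 and 1 adjusted over the list alone, with a list adjusted p of 0.0738. Of 18 HIF1 targets 2 fell, NDRG1 (-0.89 ± 0.22) and BNIP3 (-0.72 ± 0.21), and none rose (list adjusted p = 0.473). BNIP3 lost its call in 3 omissions, with an adjusted p of 0.145 without siAPE1 replicate 2, and NDRG1 one of 0.0766 with DESeq2. Of 12 mesenchymal and matrix genes MMP14 rose (0.46 ± 0.14), with an adjusted p of 0.147 without siAPE1 replicate 3 (list adjusted p = 0.550). Of 81 ribosomal protein genes RPS27L rose (0.70 ± 0.10) and 80 did not pass (list adjusted p = 0.118). In lists for which no such count is given, the calls adjusted over the list alone were as many as those over all genes.

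Few markers of cell types had enough counts to be tested, so they can say little about a mixed sample at this depth. No endothelial or immune marker had enough counts to be tested. COL6A3 was the 1 tested stellate and fibroblast marker (log2 fold -0.06 ± 0.11) and FOXA2 the 1 tested hepatocyte gene (0.10 ± 0.17). COL6A3 lay at 48.1 CPM with scramble siRNA and 45.9 CPM in the libraries labelled siAPE1. A fold between groups does not show a mixture that both share. Of 4 tested interferon-stimulated genes, including ISG15 (-0.46 ± 0.25) and STAT2 (-0.33 ± 0.29), none passed (edgeR).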

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

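The tests of the APEX1 pattern, of the Y RNA share, including that against vault RNAs, and of the chance of single lists were chosen after the result was seen. Of 268 groups of 4 libraries checked for a value far from the other 3, 15 had one (5.60%), where chance flags about 1 in 20. Gap over range was 0.942 for APEX1 in scramble replicate 4 (77.0 CPM against 86.5 to 87.1) and 0.955 for MIR769 in scramble replicate 4 (5.29 CPM against 9.25 to 9.44). It was 0.855 for AKAP12 in scramble replicate 4 and 0.836 in siAPE1 replicate 2, 0.872 for DYRK2 in siAPE1 replicate 4, and 0.830 for MIRLET7A1 in scramble replicate 1. It was 0.845 for MIR221 in scramble replicate 2, 0.948 for HMGB1 in siAPE1 replicate 1, 0.895 for SLC7A11 in siAPE1 replicate 2 and 0.832 for FDPS in scramble replicate 4. It was 0.890 for RPS21 in siAPE1 replicate 2, 0.887 for MT-ATP6 in scramble replicate 3 and 0.854 for SNORD53 in scramble replicate 4. Among shares of counts it was 0.834 for miRNA genes in siAPE1 replicate 2 and 0.862 for Y RNAs in scramble replicate 3, whose 0.550% was still below each library labelled siAPE1.

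APEX1 was 80.1-fold higher where its label calls for a fall. A change of the whole locus is argued against: the 4 tested genes within 50 kb had a median log2 fold of 0.11 (SD 0.50), from -0.47 for PNP to 0.74 for PIP4P1, which overlaps the end of APEX1. A candidate explanation is that the siRNA molecules themselves, which match APEX1, were sequenced in these small-RNA libraries and counted for the gene at 80.1 times the control level. Exchanged labels may also account for it, but APEX1 then ranked 1 among 6245 nuclear protein-coding genes in unsilenced cells, above RPS14 at 3289 CPM, against rank 277 under the scramble label. These 2 explanations cannot be told apart here, because read positions were not analysed and no untreated library was used, and biological upregulation was not tested.

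Y RNAs took 2.00 times the share of counts in the libraries labelled siAPE1, which argues against reads merely divided otherwise among copies. A gain of all short RNA by the same factor is argued against by the log2 ratio of Y RNA to miRNA share, which was 1.07 higher (from -2.01 ± 0.10 to -0.94 ± 0.05, SD, n = 4 each, exact permutation p = 0.0286). A smaller gain shared by several classes stays open. Of spliceosomal snRNAs 18 of 64 were higher and none lower, and of box C/D snoRNAs 18 of 74 and none, while miRNA genes had 2 higher and 7 lower. The summed shares of the first 2 classes had ratios of 1.09 and 1.04. Vault RNAs of like length did not rise with Y RNAs (VTRNA1-1 spans 98 bases, RNY4 96 and RNY3 102): the log2 ratio of Y RNA to vault RNA share was 1.04 higher (from 1.12 ± 0.37 to 2.16 ± 0.28, SD, n = 4 each, exact permutation p = 0.0286). Some spliceosomal RNAs near RNY1 in length (113 bases) were higher too, though by less. RNU5A-1 and RNU5B-1, of 117 bases each, had log2 folds of 0.84 and 0.93, against 1.33 for RNY1. A length-dependent yield therefore stays open. With all libraries thinned to equal totals the list median was 0.52 (adjusted p = 5.75e-13, camera), so the call did not need the extra scramble reads. Random thinning keeps each library's expected proportions, so the median could hardly have fallen. It cannot test a difference between libraries that went with depth, in which the groups did not overlap. Chance could not be excluded for the list as a whole: 3 of 35 splits of the 8 libraries gave a camera p as small, with 5.80e-14 for the real split and 2.19e-17 as the smallest of the others. A response of the cells stays open and was not tested.

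Cholesterol biosynthesis genes had a median log2 fold of 0.55 in the libraries labelled siAPE1. A gene length trend is argued against, since this median lay at percentile 100 of 10000 random lists matched on gene span and mean expression, the middle 95% of which spanned -0.18 to 0.13. The scaling on abundant short RNAs is argued against too, with a median of 0.56 without short RNA and mitochondrial classes. After thinning the median was 0.55, but thinning keeps expected proportions and so cannot test a difference between libraries that went with depth. Of 35 splits 1, the real one, gave a camera p as small (9.73e-12, against 1.43e-06 as the smallest of the others). This argues against a chance division of the libraries for this list only when taken singly. A share of 1 in 35 is the smallest these splits allow, it was not adjusted over 26 lists, and 16 other splits also passed an adjusted p of 0.05 for this list. A response of the cells may account for the rise as a hypothesis, though the group of 4 libraries cannot separate silencing from other effects of this siRNA.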

How the results depend on the processing

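Thinning and the fit without APEX1 were chosen after seeing the data. No gene called by edgeR was called in the other direction in any setting, and the log2 fold of APEX1 ranged from 6.22 to 6.40. The stricter filter tested 1752 genes and called 404 (206 higher, 198 lower; 5 miRNA genes adjusted over the list alone). DESeq2 called 260 (134 higher, 126 lower, 258 shared with edgeR, 2 miRNA genes, and 2 over the list alone). The test against 1.2-fold called 270 (135 higher, 135 lower, 3 miRNA genes, and 3 over the list alone). Leaving out 1 library called 516 to 695 genes, 267 to 350 higher and 249 to 345 lower, with the fewest without siAPE1 replicate 2. It called 4 to 10 miRNA genes, 3 to 10 over the list alone. Total-count scaling called 702 genes, 442 lower, and moved the median log2 fold of all genes to -0.05. Thinned libraries gave 632 calls, 599 shared, and leaving out APEX1 754. Replicate numbers did not pair the samples: same-numbered libraries had correlations of -0.05, -0.06, -0.06 and 0.07 over 1752 genes, and the replicate block called 731. Of 82 named genes called besides APEX1, 53 stayed called in all settings that tested them, 27 lost the call with DESeq2 and 20 in at least 1 omission.

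Lists called fell from 10 to 5 without the short RNA and mitochondrial classes, whose lists were then removed, and to 1 with an estimated correlation. That setting gave adjusted p-values of 0.186 for unfolded protein response chaperones, DNA replication and Y RNAs, 0.361 for G2/M, 0.210 for histones, 0.557 for box C/D snoRNAs, 0.550 for small Cajal body RNAs, 0.524 for spliceosomal snRNAs and 0.378 for nuclear rRNAs. Without a filter spliceosomal snRNAs had 0.116 and NF-kappaB targets 0.00663. With the stricter filter chaperones and small Cajal body RNAs had 0.107, and with total-count scaling the latter had 0.0602. By fry the lists not passing were box C/D snoRNAs (0.154), small Cajal body RNAs (0.0811), spliceosomal snRNAs (0.118) and nuclear rRNAs (0.0739), while NF-kappaB targets (0.0284), miRNA host transcripts (0.0284) and immediate early genes (0.00965) passed. With voom, box H/ACA snoRNAs and mitochondrial tRNAs had 0.0225 each, and mitochondrially encoded mRNAs, signed for a fall, -0.0273. Leaving out 1 library gave NF-kappaB targets 0.0416 to 0.137 (without siAPE1 replicates 4 and 1) and ATF4 targets 0.0499 to 0.262 (without siAPE1 replicates 2 and 3). Without scramble replicates 1 and 4 it gave box H/ACA snoRNAs 0.00529 and 0.882, small Cajal body RNAs 0.00891 and 0.218, and mitochondrial tRNAs 0.00697 and 0.486.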

Other observations

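Keratins and metallothioneins were chosen after their values were seen. Directions are by label, and APEX1 counts rose where the siAPE1 label calls for a fall. Keratins were the 1 family called among 190 gene families grouped by symbol, with 4 of 6 tested members lower in the libraries labelled siAPE1 (adjusted p = 0.000516 by camera, adjusted p = 0.986 with an estimated correlation). Besides KRT7 and KRT80, KRT18 fell from 80.2 to 48.0 CPM and KRT81 from 16.5 to 5.41 CPM, while KRT8 had a log2 fold of -0.47 ± 0.18 and KRT10 of 0.15 ± 0.17 and neither passed. Both metallothioneins tested were higher: with MT1E, MT2A rose (1.25 ± 0.13 SE, adjusted p = 1.54e-08, edgeR with Benjamini-Hochberg adjustment).

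For the number of genes called, 1 of 35 splits of the 8 libraries into 4 and 4, the real one, called as many as 756. The highest other split called 0 (535 genes with an unadjusted p under 0.05). Other splits mix the groups, which widens the spread within each, and 1 of 35 is the smallest share possible. The splits thus argue against a chance division of these 8 libraries, but not against a chance difference between the 2 sets of samples. For the 9 miRNA genes called, 1 of 35 splits called as many, but since no other split called any gene this adds nothing for miRNA genes alone, and chance was not excluded for them. It was not excluded for the number of lists called by camera, since 6 of 35 splits called at least the real 10 and the highest called 12. By list, a camera p as small as the real one came from 11 of 35 splits for box C/D snoRNAs and for spliceosomal snRNAs, 8 for small Cajal body RNAs and for nuclear rRNAs, 4 for DNA replication, 3 for G2/M, and 2 for histones, so camera's own p is weak evidence for these lists. For unfolded protein response chaperones it was 1 of 35, as for cholesterol biosynthesis, but by a small margin (0.000843, against 0.000852 as the smallest other) and with no adjustment over 26 lists.

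It was also asked whether miRNA genes change with the genes that host them. Over 17 host genes with 23 tested miRNA genes, the correlation of log2 folds was -0.152 (Spearman, permutation p = 0.558, 95% bootstrap interval -0.713 to 0.447) and -0.352 (Pearson, permutation p = 0.164), the larger adjusted p of the 2 being 0.558. Without the 2 host genes farthest from the median, Pearson's r was 0.116. The list of pairs was partial: the tested hosts MIR222HG, which spans MIR221 and MIR222, and MIR23AHG, which spans MIR27A, were not in it. These are correlations across genes, which are not independent replicates, and the interval leaves a moderate relation of either sign open. MIR33A (0.29 ± 0.27) and its host SREBF2 (0.45 ± 0.13) had the same sign, while MIR26A2 had a log2 fold of 0.69 and its host CTDSP2 of -1.10.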
